A study of Rattus norvegicus with 6 samples.

How the data were processed

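Total RNA from the junctional zone of the rat placenta, dissected on gestation day 18.5 from Brown Norway (BN) and Holtzman-Sprague Dawley (HSD) rats, was hybridised to Affymetrix 1-colour oligonucleotide arrays. Each strain had 3 arrays, which the labels call biological replicates, and females had been mated with males of their own strain. The labels do not say whether a replicate is 1 placenta, a litter or a pool, so the p-values cover the spread between samples so labelled. RNA was extracted with Trizol and checked on a Bioanalyzer, per the labels' protocols. The strain and the replicate number of each sample came from its label.

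The deposited values are signal intensities on a linear scale, 1 per probe set and array, and the submitters' processing notes name MAS5, the Affymetrix algorithm that summarises the probe pairs of a probe set. Its version and its background and scaling settings are not given in the sources used here. The mean after trimming 2% of the values at each end was 500 on every one of the 6 arrays, so the arrays had been scaled to a common level before deposit. No detection calls were used, so which signals lie above background is unknown. No value was zero or negative. For arrays there is no read depth, and the number of arrays limits the precision.

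The table held 31099 probe sets. After 57 control probe sets were left out, 31042 remained. A probe set was kept when at least 3 of the 6 arrays gave a signal at or above that array's own median, whatever the strain, which kept 15859 probe sets (51.1%). Signals were taken as log2(signal + 10.0), where the pseudocount is the 10th percentile of all deposited values. Differences are therefore on the log2(signal + pseudocount) scale, which understates the change of dim genes, and folds in the text are this difference turned back to a ratio. No further normalization was applied.

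Gene symbols came from the platform's annotation and were checked through Entrez identifiers against a table of rat genes of assembly GRCr8, in which 20764 of the 20832 probe sets with 1 symbol were found and 0 symbols changed. Of the non-control probe sets, 20826 had 1 symbol, 436 had several and 9780 had none. Probe sets with several symbols or none were tested but not named. A gene was represented by its kept probe set with the highest mean log2 signal, which gave 9345 genes. No genome build is named for the array, so no coordinates are given, and the assembly served for names and gene order alone.

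The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with no covariate, as BN minus HSD, 2-sided. P-values were adjusted by the Benjamini-Hochberg method over all 15859 probe sets, and the threshold was an adjusted p of 0.05. Gene lists were tested on the gene-level values with camera at its preset correlation between genes of 0.01, adjusted over the 24 lists tested. Beside it stand camera with an estimated correlation and fry, whose directional test asks whether a list's genes move on balance one way and whose mixed test asks whether they change in either direction. Counts adjusted over the list alone were made for each list.

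The groups, the tests, the 25 gene lists (853 symbols, 725 of them on the array, 16 of these through a synonym), the alternatives and the rule for named genes were all fixed before the data were examined. The rule names the 12 genes with the largest difference in each direction among those that passed and whose 3 signals in one strain all lay above the 3 of the other, without symbols that begin with LOC or RGD and clone names. It also names up to 4 passing members of each list in each direction, or the member with the smallest p where none passed, and 12 genes chosen by name. Genes named outside this rule are marked as chosen after their values were seen.

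The same code was tested on simulated values with the means and residual spreads of the 15859 probe sets. With equal noise on the 6 arrays, the spreads came from the fit of all 6. Of probe sets changed by 1 on the log2 scale 12 of 67 were recovered, of those changed by 2, 45 of 67, and by 3, 64 of 66. In that setting 3 unchanged probe sets were called. A second setting took the spreads of the fit without HSD replicate 3 and raised the noise on that array 2.20 times. This factor is the SD of its deviations from the other HSD arrays over the median of such SDs on the other arrays. These numbers were then 22 of 67, 51 of 67 and 59 of 66, with 2 unchanged probe sets called. The base spreads differ, so the 2 settings do not show what a noisier array does to recovery. Of 24 simulated lists over 9345 genes, the 1 shifted list was called and 0 others. The simulated genes varied independently of each other, with equal noise on the 6 arrays. Estimated correlations within the real lists reached 0.78, so the 0 does not show how often camera calls unshifted lists in these data.

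Alternatives were another pseudocount (0, or the 25th percentile, 40.9), quantile normalization, median centring, no filter, a filter at the 70th percentile, eBayes without the trend, array quality weights, the replicate number as a block, leaving out each array, plain probe sets alone (names without a cross-hybridisation suffix), the mean of a gene's probe sets, a false discovery rate of 0.01, and other list tests. The plots were drawn with matplotlib.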

Results

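The junctional zone is the layer of the rat placenta between the labyrinth, where exchange takes place, and the maternal decidua. It holds spongiotrophoblast cells, trophoblast giant cells and glycogen cells, and it is a main site of placental hormone production. Gene expression in this layer on gestation day 18.5 was measured on 6 arrays, 3 from the inbred BN strain and 3 from HSD rats. The comparison asks which transcripts differ between the strains.

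Trophoblast hormone and marker genes gave high signals in both strains. Tpbpa, a spongiotrophoblast marker, gave a mean signal of 54960 ± 3855 in BN and 55325 ± 10677 in HSD (SD, n = 3 each). The placental lactogen Prl3b1 gave 43773 ± 4287 and 48878 ± 12429, and the cell cycle inhibitor Cdkn1c gave 45934 ± 4716 and 46351 ± 5447. None of these genes passed the test (adjusted p = 0.993, 0.810 and 0.983, limma). Of 30 hormone and marker genes examined for brightness, 18 lay over 50% of the array's highest signal on every array, and their log2 differences ran from -0.29 to 0.05. Signals this near the top of the scale limit how much of a difference the array can show.

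HSD replicate 3 stood apart from the other arrays. Its log2 signals correlated with theirs at Pearson r of 0.8803 to 0.9018 (Spearman 0.877 to 0.890), against 0.938 to 0.976 (Spearman 0.920 to 0.935) among the other 5 arrays, across probe sets that are not independent replicates. On it, 1492 of 9345 genes lay over 2-fold from the mean of the other HSD arrays, while this number was 96 to 621 on the other arrays. The ratio of the 3' to the 5' control probe set of beta-actin was 2.60 on this array and 1.42 to 1.66 on the others.

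**Figure D1:**
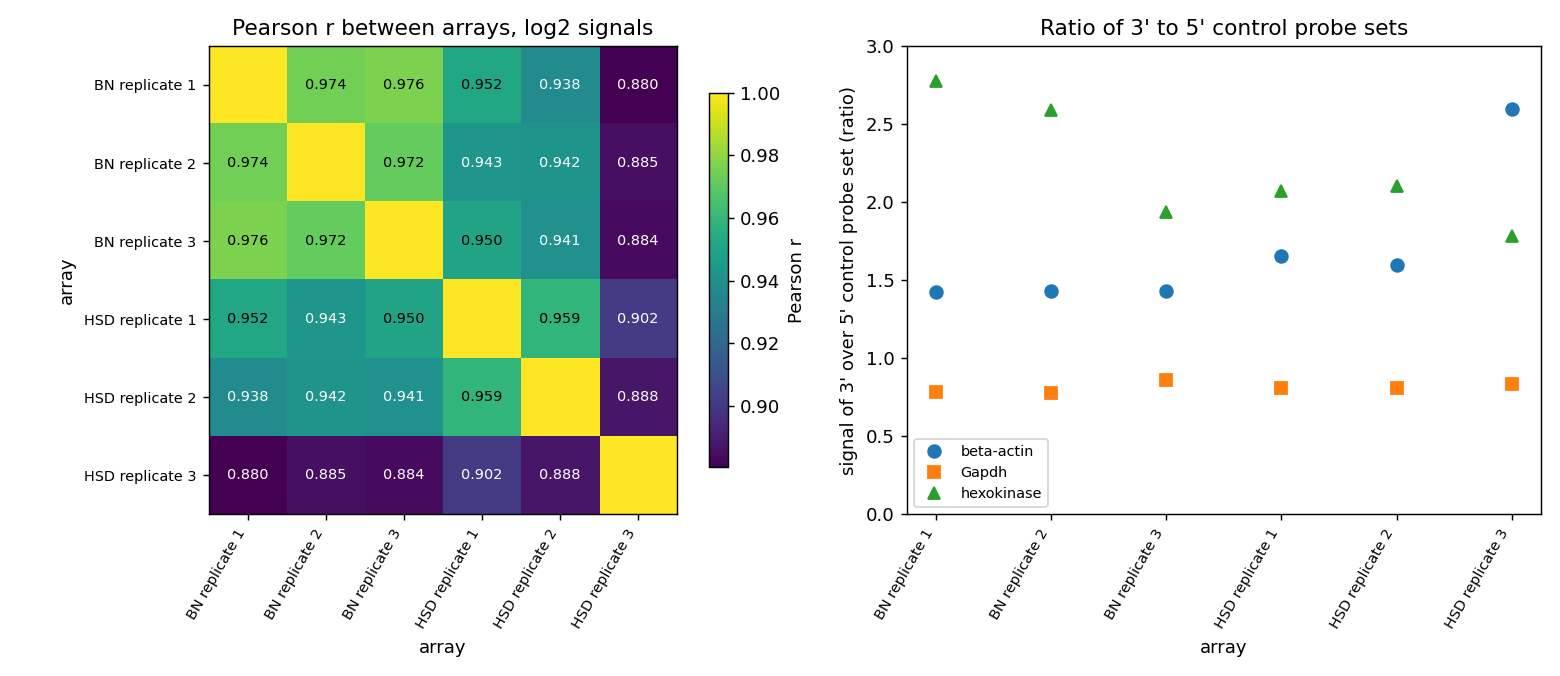
The left panel shows Pearson r between the log2 signals of each pair of the 6 arrays, and the right panel shows, per array, the ratio of the 3' to the 5' control probe set for 3 control transcripts. HSD replicate 3 has r of at most 0.902 with the others and the highest beta-actin ratio (2.60), whereas its Gapdh ratio (0.834) lies within the range of the others and its hexokinase ratio (1.78) is the lowest.

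Between the strains, 133 of 15859 probe sets passed an adjusted p of 0.05, with 38 higher and 95 lower in BN, and 132 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 2038. At the gene level 76 of 9345 genes passed, 24 higher and 52 lower in BN. All 133 probe sets separated the 3 BN from the 3 HSD arrays, as did 21.2% of all kept probe sets, where chance gives 10%. The count depended on single arrays. It was 700 without HSD replicate 3 (285 higher, 415 lower), and all 133 were among these in the same direction. It was 32, 33 and 34 without BN replicates 1, 2 and 3, and 60 and 78 without HSD replicates 1 and 2. With array quality weights it was 823. The corresponding gene counts were 422 without HSD replicate 3, 16, 16 and 18 without the BN arrays, 29 and 47 without HSD replicates 1 and 2, and 506 with weights.

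By each gene's brightest kept probe set, the gene with the largest difference was Echdc2, which encodes a mitochondrial enoyl-CoA hydratase domain protein. Its signal was 24.7 ± 24.3 in BN and 1878 ± 274 in HSD (SD, n = 3 each), a log2 difference of -6.01 ± 0.48 (SE, adjusted p = 0.00165). Next among the genes lower in BN came RT1-T24-4, an MHC class I gene, at -4.01 ± 0.50 (adjusted p = 0.00896), and Prr5l, whose product binds the mTOR kinase complex, at -3.71 ± 0.21 (adjusted p = 0.000444). Secreted proteins were encoded by the thrombospondin gene Thbs4, which fell by 3.69 ± 0.56 on the log2 scale, by the serine protease homologue Prss35 (-3.45 ± 0.57), the protease inhibitor Slpi (-2.77 ± 0.30) and the fibulin Efemp1 (-2.67 ± 0.26). The signals of Thbs4 and Prss35 on HSD replicate 3, 303 and 363, lay far below those on the other HSD arrays, 926 and 1670 for Thbs4 and 1807 and 1060 for Prss35. Without this array their folds rose from 12.9 to 20.5 and from 10.9 to 16.9. The fold also rose for Slpi, Ramp3 and Efemp1. It fell for the rest of the 12 named as lower in BN, for Asgr1 from 10.5 to 7.98. Cell surface and signalling proteins were encoded by other genes lower in BN, with log2 differences of -3.40 for the asialoglycoprotein receptor subunit Asgr1, -2.90 for the kinase Txk, -2.74 for the adrenomedullin receptor partner Ramp3 and -2.61 for the small GTPase Rem1. Fam111a, which encodes a protease that acts at replicating DNA, differed by -2.87. The BN signals of Echdc2, Asgr1, Txk, Rem1 and Thbs4 averaged 53.7 or less, so the pseudocount understates their folds, and whether those signals lay above background is unknown. The same holds for Oas1b and Npas3, higher in BN, whose HSD signals averaged 52.1 and 50.2. The order of genes depends on the probe set. Krt6c, a keratin gene named after its values were seen, differed by -2.18 on its brightest probe set and by -4.10 and -5.09 (adjusted p = 0.000444 and 0.00165) on 2 others. A dimmer probe set of Sppl2a, a protease gene also named after its values were seen, differed by -4.74 (adjusted p = 0.000893) while its 3 other kept probe sets gave -0.44 to 0.02. The adjusted p of the 12 genes named in each direction was at most 0.0479.

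Among genes higher in BN, Ccn1, a matricellular protein gene, had a signal of 5022 ± 1204 in BN and 509 ± 253 in HSD, a log2 difference of 3.41 ± 0.40 or 10.6-fold (adjusted p = 0.00763). Oas1b, an oligoadenylate synthetase gene of the interferon response, followed at 3.28 ± 0.37 (adjusted p = 0.00598). The protein disulfide isomerase Pdia5 differed by 3.12 ± 0.53 and the transcription factor Npas3 by 2.75 ± 0.34. The gelatinase Mmp9 had signals of 808 ± 173 and 155 ± 77.6, a 5.29-fold difference (adjusted p = 0.0253). Cdhr2, a cadherin of microvilli, differed by 2.29 ± 0.25, the neuronal pentraxin Nptx1 by 2.14 ± 0.31, the MHC class II chain RT1-Ba by 2.11 ± 0.31 and the complement protease C1s by 1.98 ± 0.20. The kinase Sik1 (1.71 ± 0.29) and Spp1, the gene of osteopontin (1.67 ± 0.26), stood with the hormone gene Prl5a1 among the 12. Without HSD replicate 3 the fold fell from 10.6 to 7.46 for Ccn1 and from 5.29 to 4.03 for Mmp9. The fold rose for Npas3, Prl5a1 and Sik1 and fell for the rest of the 12. A second probe set of Sik1 gave 0.28 (adjusted p = 0.678). Of 20 other kept probe sets of passing genes, 19 went the same way, the exception being 1 of Sync (-0.35 against 1.26), a gene named here after its values were seen. Of the 28 named genes that passed, 10, 10 and 11 also passed without BN replicates 1, 2 and 3, 14 without HSD replicate 1, 22 without HSD replicate 2 and 28 without HSD replicate 3.

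**Figure D2:**
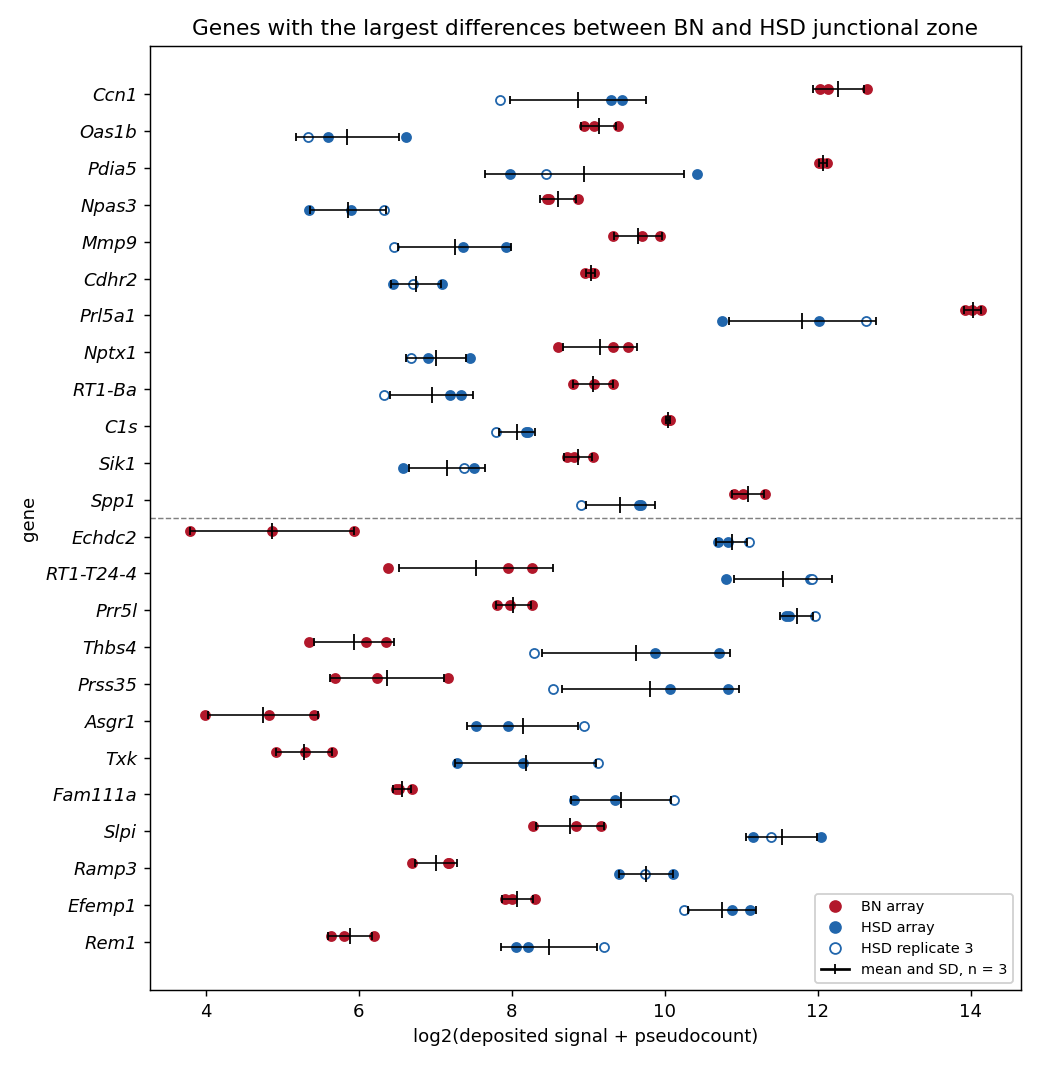
Each row is a gene, and each point is the log2(signal + pseudocount) of 1 array, red for BN and blue for HSD, with HSD replicate 3 as an open circle. Black bars are the mean and SD of 3 arrays. The 12 genes above the dashed line are higher in BN (Ccn1, log2 difference 3.41, at the top) and the 12 below are lower (Echdc2, -6.01, first), and in each the 3 BN points lie apart from the 3 HSD points.

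Of 18 measured prolactin family hormones, which are made by trophoblast and the decidua, 1 rose and 1 fell. Prl5a1 was 4.67-fold higher in BN (16680 ± 1221 against 4057 ± 2303, adjusted p = 0.0479), and Prl3a1 was 3.37-fold lower (1887 ± 336 against 6702 ± 2578, adjusted p = 0.0419). Adjusted over the list alone, 1 rose and 3 fell, and Prl2b1 (-1.37 ± 0.29) and Prl3c1 (-1.40 ± 0.43) were the added ones. List members named here and in the following groups for passing over the list alone were chosen after their values were seen. The family members Prl8a2 and Prl8a9 differed by -0.17 ± 0.24 and -0.13 ± 0.20 (adjusted p = 0.808 and 0.822). Prl7b1 differed by 0.28 ± 0.60 on the log2 scale, although its mean signal was 11029 in BN and 12145 in HSD, because 26006 on HSD replicate 3 raised the HSD mean, and without this array it differed by 1.07 (adjusted p = 0.0560). Without it Prl8a2 and Prl8a9 turned to 0.11 and 0.09 (adjusted p = 0.682 and 0.696). The list median on HSD replicate 3 lay 0.75 above the other HSD arrays. The highest signal on that array was itself 83616, against 56846 and 52889 on HSD replicates 1 and 2. A CreX control probe set gave 39879 there, against 30201 and 27478. On every array 8 of the 18 members lay over 50% of the highest signal. Their shift cannot be separated from the higher top of the scale on that array. As a set the list did not pass (median -0.13, adjusted p = 0.331, lower in BN). Without HSD replicate 3 its median was 0.13 (adjusted p = 0.560, higher in BN), a turn to which the same limit applies, and it passed as lower without HSD replicate 2 (adjusted p = 0.0150), where replicate 3 is 1 of the 2 HSD arrays left. No gene among 8 pregnancy-specific glycoproteins and related placental CEACAMs passed, adjusted over all probe sets or over the list alone, 0 had an unadjusted p under 0.05 (limma), and the smallest p was that of Psg29 (-0.29 ± 0.16, adjusted p = 0.483). That list lay 0.53 higher on HSD replicate 3. With 6 of its 8 members over 50% of the highest signal on every array, this shift cannot be separated from the higher top of that array's scale. Signals so near the top also limit what the lack of passing members shows. Members of these families share sequence, so cross-hybridisation between them cannot be ruled out.

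Among 22 measured junctional zone trophoblast markers, 1 rose (Mmp9) and 0 fell, and 2 rose when adjusted over the list alone, the other being the placental gene Plac1 (0.997 ± 0.22). The list's median log2 difference was 0.25, and camera placed it higher in BN than other genes (adjusted p = 0.0110). The labyrinth trophoblast markers had a like median (0.26, 15 of 19 higher in BN) but did not pass (camera, unadjusted p = 0.0277, adjusted p = 0.161). Without HSD replicate 3 the medians were 0.15 for labyrinth and 0.19 for junctional zone markers. The 2 lists were not tested against each other, so whether the shift was particular to junctional zone markers is unknown. The junctional zone call was lost with an estimated correlation (adjusted p = 0.668), without HSD replicate 1 (adjusted p = 0.136), without HSD replicate 3 (adjusted p = 0.0817) and with the stricter filter (adjusted p = 0.0601). The spongiotrophoblast regulator Ascl2 differed by 0.29 ± 0.31 and Flt1, a VEGF receptor and also a spongiotrophoblast product, by 0.64 ± 0.29 (adjusted p = 0.733 and 0.403). None of 5 placental cathepsins, proteases of giant cells, passed over all probe sets, and 4 had an unadjusted p under 0.05 (limma). Adjusted over the list alone, 1 rose (Ctsj, 0.44 ± 0.18) and 3 fell (Ctsql2, -1.14 ± 0.21; Ctsr, -0.85 ± 0.26; Ctsq, -0.74 ± 0.17), and the last 3 passed over all probe sets without HSD replicate 3.

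Of 16 measured macrophage and neutrophil markers, 1 rose, the leukocyte integrin chain Itgb2 (1.16 ± 0.20, adjusted p = 0.0371), and 0 fell. Adjusted over the list alone, 7 rose and 1 fell. The other members that rose there were the receptor adaptors Tyrobp (1.30) and Fcer1g (1.16), the Fc receptor Fcgr2b (1.35), the chemokine receptor Cxcr2 (1.10), the lysozyme gene Lyz2 (0.999) and the leukocyte antigen Ptprc (1.34), and the one that fell was the macrophage antigen Cd68 (-1.70 ± 0.34). The list median was 0.49. The list passed with camera (adjusted p = 0.0110), also without HSD replicate 3 (adjusted p = 0.00624). It did not pass with an estimated correlation (adjusted p = 0.668), without HSD replicate 1 (adjusted p = 0.136) or with the stricter filter (adjusted p = 0.261). The estimated correlation of this list was 0.0205, near the preset 0.01, while the unadjusted p went from 0.000921 to 0.0359 (camera). For the placental cathepsins the estimated correlation (-0.013) lay below the preset, yet the unadjusted p went from 0.0157 to 0.0694 (camera). The 2 forms of the test therefore differ in more than the correlation. The lost call does not show that the preset was too low for the macrophage and neutrophil list. With estimated correlations the smallest adjusted p of any list was 0.668, so that test set no list apart. The list lay 0.35 lower on HSD replicate 3 than on the other HSD arrays.

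No other list passed with camera, and 0 of the 24 passed with an estimated correlation or with fry's directional test, while 8 passed fry's mixed test. At an unadjusted p under 0.05 these numbers were 1 with an estimated correlation and 4 with fry's directional test. The mixed test does not compare a list with other genes. Of all 9345 genes, 1198 had an unadjusted p under 0.05 (limma), so a list can pass it without standing out. In the list of matrix metalloproteinases, their inhibitors and the plasminogen system, 2 of 29 members rose (Mmp9 and Spp1) and 1 fell, the stromelysin Mmp10 (-2.10 ± 0.26, adjusted p = 0.00844). Over the list alone 6 rose, among them the urokinase gene Plau (1.06), and 3 fell, with Mmp2 (-1.77) and the inhibitor gene Timp1 (-1.13) beside Mmp10. Fry's mixed test gave an adjusted p of 0.000677 for this list, which lay 0.43 lower on HSD replicate 3. Of 26 MHC and antigen processing genes, 2 rose (RT1-Ba and RT1-CE16, the latter 1.37 ± 0.22) and 1 fell (RT1-T24-4), and over the list alone 5 rose and 1 fell. Its median (-0.01) was below 0 while its mean (0.10) and camera's direction were above. RT1 genes differ in sequence between rat strains and share sequence with each other, so their signals are uncertain as measures of transcript level. Of 38 interferon response genes 1 rose (Oas1b), and over the list alone 2 rose and 1 fell (Ifit2, 1.42, and Ifit1, -1.12).

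No member of the remaining lists passed over all probe sets on its brightest probe set, while a dimmer one of Txnrd1 did (1.09, adjusted p = 0.0422). Of 16 steroid hormone genes, 3 rose over the list alone, namely Cyp17a1, the steroid hydroxylase and lyase (0.85 ± 0.21), the cholesterol carrier Star (0.76) and the electron donor Por (0.81). Without HSD replicate 3, 4 passed over all probe sets, with Cyp11a1 and Fdx1 beside Cyp17a1 and Star. Over the list alone, 2 of 28 imprinted genes fell, the deiodinase Dio3 (-1.06 ± 0.21) and the proteoglycan Dcn (-1.35 ± 0.28), and Igf2 and Phlda2 differed by 0.18 ± 0.16 and 0.19 ± 0.30. Vegfb was the 1 of 17 angiogenic genes to fall over the list alone (-1.62 ± 0.30), and Txnrd1, thioredoxin reductase, the 1 of 43 glutathione and antioxidant genes to rise (1.04 ± 0.21). Over the list alone 0 members passed among 19 glycogen metabolism genes (smallest p, Stbd1, -0.80 ± 0.19), 37 cell cycle genes (Mcm2, -0.83 ± 0.20), 34 hypoxia and glycolysis genes (Egln3, 0.79 ± 0.25), 19 cholesterol synthesis genes (Fdft1, -0.45 ± 0.20), 26 transporters (Slc43a1, -1.07 ± 0.34) and 30 genes of the unfolded protein response (Sdf2l1, -0.86 ± 0.21). In these 6 lists 4, 4, 4, 0, 1 and 3 members had an unadjusted p under 0.05 (limma).

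Markers of neighbouring tissues were measured as well. Over the list alone, 2 of 19 labyrinth trophoblast markers rose (the transferrin receptor Tfrc, 0.89 ± 0.19, and the iron exporter Slc40a1, 0.91) and 1 fell (Epcam, -0.79). Of 30 decidual and stromal markers 2 rose (Col3a1, 1.05, and Tagln, 1.21) and 2 fell (Dcn and Fbln1, -1.01), and of 10 yolk sac markers 1 rose (Ctsz, 0.87) and 1 fell (Amn, -1.20 ± 0.26). Without HSD replicate 3 the decidual and stromal median turned from 0.23 to -0.16, and over all probe sets 0 of its members rose and 3 fell. None of 10 endothelial (Esam, 0.65 ± 0.28), 16 erythroid (Rhd, -1.02 ± 0.48) or 6 natural killer and T cell markers (Il2rb, 0.39 ± 0.18) passed over the list alone, and 1, 0 and 0 had an unadjusted p under 0.05 (limma). HSD replicate 3 lay below the other HSD arrays by list medians of -0.89 for endothelial, -0.86 for angiogenic, -0.71 for labyrinth -0.69 for decidual and stromal genes and -0.43 for transporters, and above them by 0.59 for natural killer and T cell and 0.42 for erythroid markers. Xist, the transcript of the inactive X chromosome (0.44 ± 0.20, adjusted p = 0.408), gave signals of 5317 to 9762. Of genes on the Y chromosome, 1 probe set of Uty gave 1781 to 2367, while the other of Uty (39.9 to 69.3) and that of Sry (11.1 to 76.6) were too dim to be kept. That of Eif2s3y (0.717 to 465) was not kept either, although its highest signal lay above the median of every array (120 to 136). Whether every array held Y chromosome transcripts, and in like amounts, is unknown.

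**Figure D3:**
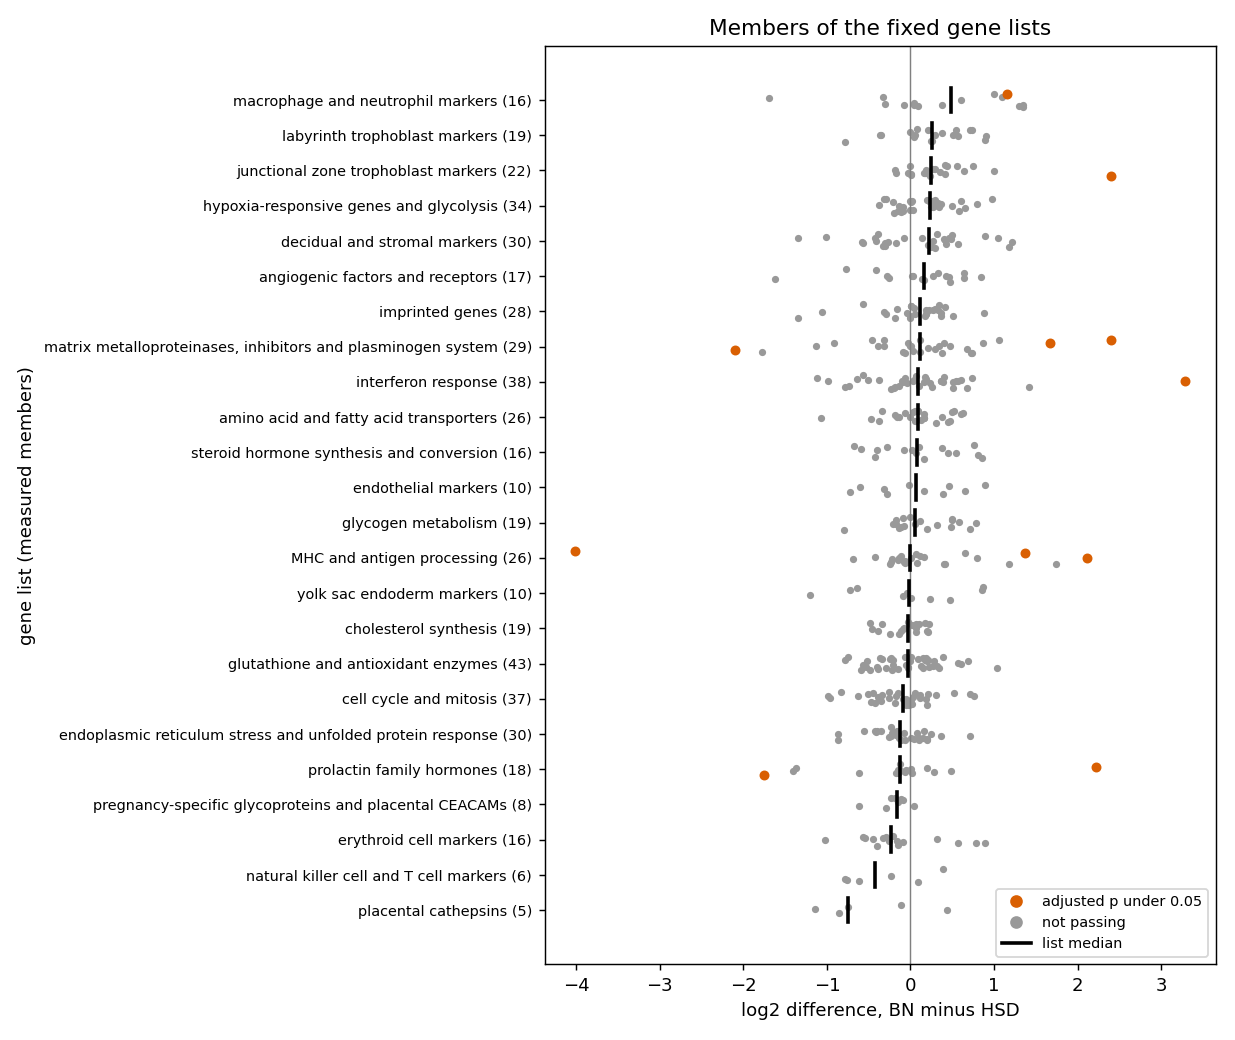
Each row is a gene list with its number of measured members, and each point is the log2 difference (BN minus HSD) of 1 member, orange where the adjusted p over all probe sets was under 0.05 and grey otherwise. Black bars are list medians, from -0.74 for 5 placental cathepsins to 0.49 for 16 macrophage and neutrophil markers.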

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

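Among the counts of differing probe sets, those at least 2-fold and genes (133, 132 and 76), both pseudocounts, quantile normalization, median centring, the stricter filter and eBayes without the trend stayed within 1.5 times, as did plain probe sets alone and the mean of a gene's probe sets. Without a filter the counts were 85, 85 and 47, with more probe sets tested. With array weights, which gave HSD replicate 3 a weight of 0.168, they were 823, 443 and 506. A false discovery rate of 0.01 left 42 probe sets. Leaving out 1 array gave 32 to 700 probe sets, 32 to 379 at least 2-fold and 16 to 422 genes, the highest each time without HSD replicate 3 and the lowest without a BN array. Each of these fits had 5 arrays, and the cause was not tested. The probe sets higher in BN made up 28.6% of the calls, 33.3% after quantile normalization and 46.1% with array weights, and leaving out 1 array gave 12.1% (without BN replicate 2) to 40.7% (without HSD replicate 3), so the balance of directions depended on the arrays and their weights.

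The replicate numbers do not show paired samples: deviations of same-numbered arrays correlated at 0.16, 0.07 and -0.01 across probe sets, and 2 of the 3 BN arrays correlated best with their own number. With the replicate block, 86 probe sets passed, 86 of them at least 2-fold, and 44 genes, and 2 lists passed.

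The 2 lists past the threshold became 0 with the stricter filter, 0 with an estimated correlation and 0 with fry, and 0 to 3 when 1 array was left out. The adjusted p of the junctional zone markers was 0.0601 with the stricter filter, 0.668 with an estimated correlation and 0.223 with fry. For macrophage and neutrophil markers these were 0.261, 0.668 and 0.0836. Leaving out 1 array gave 0.00687 to 0.136 for the junctional zone markers, 0.00624 to 0.136 for the macrophage markers and 0.015 to 0.56 for the prolactin family, which passed in 1 case, without HSD replicate 2. The cause was not tested.

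No passing named gene changed sign under any of the 16 alternatives run on it, and 25 of 28 passed at a pseudocount of 0, 20 without a filter, 22 without the trend, 22 with the replicate block and 26 with the mean of a gene's probe sets. Signs of the 29 named genes that did not pass changed in 16 of 456 values, and 8 lists changed direction in some setting. With the stricter filter 6 passing named genes were too dim to be tested and 2 of the other 22 no longer passed. Without detection calls, how far dim signals lie above background is unknown.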

Other observations

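The gene families by symbol, the genes named in this part outside the fixed rule, the tests of other probe sets, of the macrophage list and of a strain swap were chosen after the results had been seen. Without HSD replicate 3, 422 genes passed, 173 higher and 249 lower in BN, and all 76 that passed with 6 arrays were among them. In the 5 fixed lists with 4 or more passing members without this array, the numbers higher and lower in BN were 5 and 1 for MHC and antigen processing, 4 and 1 for macrophage and neutrophil markers, 4 and 0 for steroid hormone genes, 3 and 1 for interferon response genes, and 3 and 3 for matrix metalloproteinases, inhibitors and the plasminogen system.

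Of 19 gene families taken by symbol, 4 passed camera with 6 arrays and 0 without HSD replicate 3 or with an estimated correlation. Collagens (15 genes, median 0.49, adjusted p = 0.00803) and integrins (19 genes, 0.44, adjusted p = 0.0368) were higher in BN, and ribosomal protein genes (44 genes, -0.22, adjusted p = 0.0126) and replication genes such as the Mcm family (22 genes, -0.32, adjusted p = 0.00803) lower. Without HSD replicate 3 the medians were 0.07, 0.06, 0.04 and -0.23. On HSD replicate 3 the medians lay -1.35, -0.69, 0.72 and 0.23 from the other HSD arrays.

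HSD replicate 3 stood apart from the other arrays, and a different cell mix as the whole cause is argued against by genes that every cell uses: 55 such genes with long transcripts, fixed before their values were seen, lay at a median of -1.17 from the other HSD arrays (SE 0.11), 98.2% of them below 0. A swap of strain is argued against by the 700 probe sets that passed without this array, on which it lay at a median position of 0.769 (SE 0.04). On this scale the BN mean is 0 and the mean of the other HSD arrays is 1. The other arrays, each placed likewise between the other strain and its own, lay at 0.841 to 1.01, so this array lay lowest. The test fixed beforehand was a share of over 75% nearer to HSD, which at 67.4% was not met and left the question open. The median position was chosen after that share was seen. Poorer recovery of long transcripts, from RNA integrity or labelling, is a candidate explanation that met its test. On this array 71 short ubiquitous genes lay at 0.63, so that short minus long came to 1.80. It was -1.16 to 0.31 on the other arrays, where HSD replicates 1 and 2 are set against a mean that includes replicate 3. Long and short genes were not matched for brightness. The highest signal was 83616 on this array, against 56846 and 52889 on HSD replicates 1 and 2. The rise of the short genes therefore cannot be separated from this higher top of the scale, so the test does not single out transcript length. The idea came from this array's most deviating genes, which the lists leave out, and the control ratio of beta-actin went with it while those of Gapdh (0.834) and hexokinase (1.78) did not. Beyond the cell mix no biological explanation was tested, and a difference in cell mix beside poorer recovery stays open.

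Some single genes differed by 10-fold or more, and a sequence variant of 1 strain under a probe set could lower its signal without a change in transcript level. For 16 genes the brightest probe set passed and others were kept. These 20 others gave a median share of 0.763 of the difference, and 19 went the same way. This argues against a variant as the general cause in these 16 genes alone. Only other probe sets of Krt6c, Acer2 and Prcp passed the threshold themselves. Those of Mmp9 (2.86, adjusted p = 0.158, limma) and RT1-Ba (2.61, adjusted p = 0.122, limma) were among those that did not. In 3 of the 20, of Sik1, Wtap and Sync, the share was under 0.25. A variant dims its own probe set, so grouping genes by their brightest probe set can move variant cases out of this group. In 10 further genes only a dimmer probe set passed, Sppl2a and Dguok among them, and the 17 other probe sets gave a median share of 0.169 (SE 0.13), 10 of them under 0.25, so there a variant stays open. Of the 76 passing genes, 60, Echdc2, Prr5l and Ccn1 among them, have 1 kept probe set, and there a variant and a transcript difference cannot be told apart without probe sequences. A genetic difference in expression between the strains also stays open.

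Macrophage and neutrophil markers passed as a list, higher in BN, with camera's preset correlation, but not with an estimated correlation (adjusted p = 0.668), without HSD replicate 1 (adjusted p = 0.136) or with the stricter filter (adjusted p = 0.261). The list's estimated correlation, 0.0205, lay near the preset 0.01, so the first loss does not show that the preset was too low for it. HSD replicate 3 as the source of the call with the preset correlation is argued against, since without it the adjusted p was 0.00624. A larger share of these cells in BN tissue may contribute, but 75% of the 16 members had a higher mean in BN and Cd68 went the other way (-1.70), so the members do not settle it.

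That genes differing between the strains lie near each other was a hypothesis tested on gene order. Among 9318 genes in order, 4 of the 76 passing genes had another within 3 measured neighbours on either side. In 10000 random draws the median was 4 and the 95th percentile 8 (permutation p = 0.550, 1-sided), so no clustering was seen.

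The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split gave 133 probe sets, 132 at least 2-fold, and 76 genes, and the highest of the other splits gave 0 in each case, so that 1 of the 10 splits gave as many. For the gene lists the real split gave 2 and the highest other 5 (BN replicates 1 and 3 with HSD replicate 2). Of the 10 splits, 7 gave 2 or more, so a count of 2 does not set the strain split apart. The other splits put arrays of both strains on each side, so each still holds part of the strain difference. Whether shared structure between arrays or a preset correlation set too low gave these calls was not tested.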
